A study of Mus musculus with 12 samples.

How the data were processed

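H3K4me3 was measured by chromatin immunoprecipitation and sequencing in 8 libraries of mouse small-intestinal epithelium, 2 for each of E12.5, E14.5, ISC and enterocytes. Per the labels' protocols, embryonic epithelium was sorted as EpCAM-positive cells negative for endothelial and leukocyte markers, stem cells were sorted for high Lgr5-EGFP from adult males, and chromatin was sonicated to fragments of 350 to 700 bp. A further 4 samples are input libraries; their own files were not used here, and they enter only as the controls of the authors' peak calls. Groups and replicate numbers were taken from the sample titles. The design text calls the 2 libraries of a stage biological duplicates.

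The deposited values are peak lists, 1 per library, with replicates not pooled. Per the file headers, peaks were called with MACS 2.0.10.20130712 in broad mode with a q-value cutoff of 0.01, an effective genome size of 1870000000, model folds of 5 to 50 and automatic handling of duplicate tags, and the 2 libraries of a group had the same input as control. The submitters' processing notes name Bowtie 1.1.2, SAMtools 1.2, bcl2fastq 1.8.4 and the build mm9. Per the file headers, each peak has a position and length in bp, a pileup signal (the mean coverage by fragments), the −log10 p-value and −log10 q-value against the input, and a fold enrichment over the input as a ratio. These are the authors' values for a single peak and were used only to rank or filter peaks within their own list. The lowest −log10 q in a list was between 1.01 and 1.09, so the lists hold broad peaks with a q above the 0.01 in the headers; the cutoff applied to broad peaks is not stated there. Depth, from the file headers, was 15053166 and 22696869 tags at E12.5, 43259380 and 22718162 at E14.5, 13355462 and 25547814 in ISC, and 12821255 and 22137910 in enterocytes. The lists give no read counts per region, so a region missing from a list is one the authors' caller did not report at that depth and not one shown to lack the mark.

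The 8 lists were merged into regions wherever peaks overlapped by at least 1 bp or touched. For each region and library the bp under that library's peaks were counted. Lists were compared by the Jaccard index, with a one-sided exact permutation test over all ways of pairing 8 libraries. Regions called in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(covered bp + 200). Covered bp was first divided by a factor per library that equalized the medians over regions called in all 8 libraries, from 0.72 for E12.5 replicate 1 to 1.28 for E14.5 replicate 2. All 4 groups were fitted together with a trended prior, so that they shared 4 residual degrees of freedom and a prior of 1.52, and calls were made two-sided at a Benjamini-Hochberg adjusted p of 0.05 per comparison. Log2 changes and their SE are on this scale, which understates changes of short regions. Where a region was called in no library of a group, the covered bp and the adjusted p are given without a log2 change. That value depends on the pseudocount, as it does where 1 of 2 libraries had 0 bp. The adjusted p depends on it too. A group with 0 bp in both libraries has no spread between them, so the adjusted p of such regions may be too small. An example is the chromosome 14 region starting at 80399966, in ISC against E14.5. Its limma adjusted p was 3.11e-05 with 50 bp, 0.000196 with 200 bp and 0.000586 with 1000 bp. Printed covered bp are unscaled. The 24 tested entries named by the fixed rule are the 3 regions with the largest change per direction and comparison, among those past the threshold whose libraries did not overlap between the groups. Regions called in all 8 libraries were named after their values were seen, from those with the largest changes that also passed with each library left out in turn.

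Gained and lost regions are those with a peak in every library of one group and in none of the other; with 2 libraries against 2 there is no test per region, and the counts were set beside those of the other splits of the same libraries. Tests, comparisons, the naming rule and the alternatives were fixed before the data were examined. The plan was to call gained and lost promoters and to test 15 gene lists by Fisher's exact test. The gene table given was for the build GRCm38, its coordinates were not used, and no conversion between builds was made, so that the same calls were made on merged regions, as the plan provided, and no gene was named. The alternatives were other pseudocounts, no scaling or quantile normalization, other minimum numbers of libraries, lists of equal number (the 11111 peaks of each list with the highest −log10 q), peaks with a −log10 q of at least 10, a minimum of 500 covered bp, reciprocal overlap of 50%, replicate number as a block, the 1000 widest peaks, and each library left out in turn.

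The limma step was tested on simulated covered lengths for 16593 regions, with known changes between enterocytes and ISC and a simulated chance of missing each peak. Among regions called in all 8 libraries it recovered 0 of 30 changes of 1.5-fold, 2 of 37 changes of 2-fold (5.4%), 27 of 37 changes of 4-fold (73%) and 41 of 50 regions from which the simulated peaks of 1 group had been removed (82%). It called 36 of 16363 unchanged regions, 33.6% of the 107 calls made, so the share of false calls exceeded the nominal level when few regions truly changed and peaks were missed at random. In this simulation, large changes in covered length were mostly recovered and changes of 2-fold or less mostly were not. Its chance of missing a peak was the same in every group. It made 107 calls, against 1330 in the data for this comparison, so it does not set the detection limit of the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the other steps. Intervals for shares are 95% Wilson intervals and cover counting error only.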

Results

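H3K4me3, a histone mark found at the promoters of active and poised genes, was measured by chromatin immunoprecipitation and sequencing in mouse small-intestinal epithelium. Cells came from 4 sources: embryonic epithelium sorted by EpCAM at the embryonic days E12.5 and E14.5, adult stem cells sorted for high Lgr5-EGFP (ISC), and adult enterocytes. Each group had 2 libraries, described in the labels as biological duplicates. The study asked how this mark changes while adult stem cells are specified in the embryo and while they differentiate. Regions are given by mm9 position, since no gene annotation of that build was used here.

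The sequenced depth of the 8 libraries ranged from 12821255 tags in enterocyte replicate 1 to 43259380 tags in E14.5 replicate 1. The peak lists held 11111 and 13693 peaks at E12.5, 16225 and 17658 at E14.5, 13213 and 15617 in ISC, and 11650 and 17007 in enterocytes (replicates 1 and 2). List length did not follow depth alone: E14.5 replicate 2 had 22718162 tags and the longest list, and E12.5 replicate 2 had 22696869 tags and 13693 peaks. Of the peaks of each replicate 1, between 96.2% and 97.9% overlapped a peak of their replicate 2. In the other direction, the share was 66.7% for enterocytes, 78.4% for E12.5, 80.8% for ISC and 90.3% for E14.5.

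A core set of regions carried the mark in every library. The 8 lists merged into 24352 regions, of which 17679 were called in at least 2 libraries and 8903 in all 8. Both libraries of a group called 10632 regions at E12.5, 15802 at E14.5, 12549 in ISC and 11239 in enterocytes. Replicates of a group resembled each other more than libraries of different groups did, with a mean Jaccard index (shared bp over union bp) of 0.731 within groups and 0.555 between groups. The difference of 0.176 was the largest of all ways to pair the libraries (one-sided exact permutation p = 0.0095, the smallest this design can give). Libraries of a group also had the same input as control, so this test cannot tell stage from a shared input. Between groups, E14.5 and ISC had a mean index of 0.631 and ISC and enterocytes 0.618. E12.5 had an index of 0.564 with ISC, 0.518 with E14.5 and 0.472 with enterocytes. The index is limited where 2 lists differ in covered length, which was 11528423 bp for E12.5 replicate 1 and 24275691 bp for E14.5 replicate 2. In lists of equal number, E12.5 had 0.593 with ISC, 0.579 with E14.5 and 0.494 with enterocytes. There E14.5 and ISC had 0.669, and ISC and enterocytes 0.648. The differences among these group pairs were not tested.

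**Figure D1:**
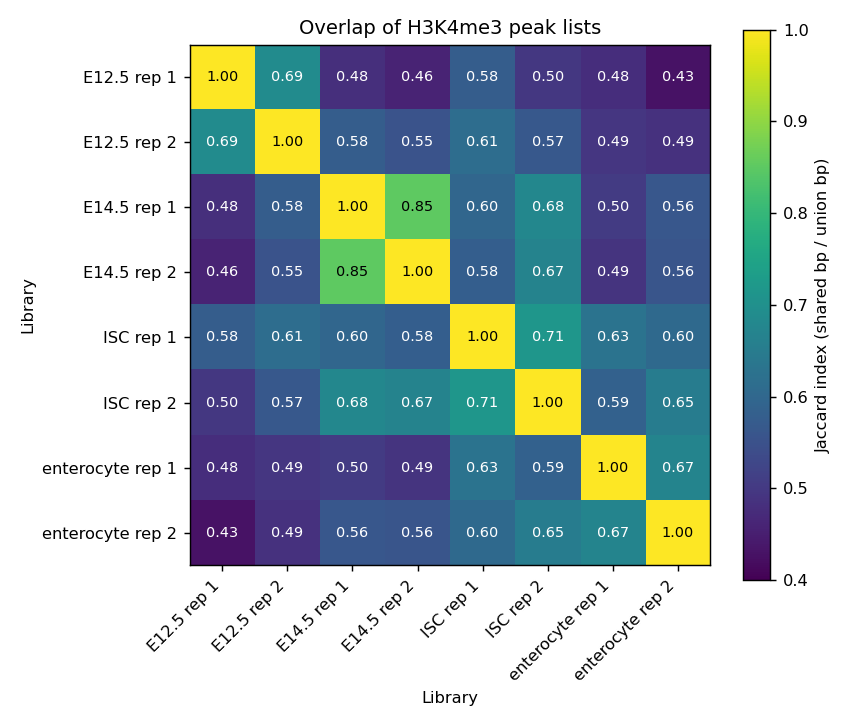
Jaccard index (shared bp over union bp) of the H3K4me3 peak lists for each pair of the 8 libraries, with libraries on both axes and the index as colour and number. The pair of E14.5 replicates has the highest index, 0.851, and the other replicate pairs have 0.67 to 0.714.

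From E12.5 to E14.5, progression of the embryonic epithelium, long H3K4me3 regions were called at E14.5 that were called in neither E12.5 library. One region, on chromosome 1 from 67158286 to 67163209, was covered over 4334.5 bp ± 408 (SD, n = 2) at E14.5 (limma, adjusted p = 0.00019). It was covered over 4403 bp ± 495 in ISC and was called in neither enterocyte library. On chromosome 19, the region from 5841400 to 5847498 was covered over 4040.5 bp ± 296 at E14.5 (adjusted p = 0.00032) and was called in all 4 adult libraries. On chromosome 7, the region from 17643403 to 17649031 was covered over 4836 bp ± 774 at E14.5 (adjusted p = 0.014), 366 bp ± 518 in ISC and 115 bp ± 162 in enterocytes. Among regions called in all 8 libraries, one on chromosome 1 from 137149762 to 137155874 lengthened from 697.5 bp ± 163 at E12.5 to 5922.5 bp ± 142 at E14.5, a log2 change of 2.16 ± 0.19 (SE, adjusted p = 0.00092). It stayed at 5727 bp ± 420 in ISC and 5594.5 bp ± 48.8 in enterocytes. That region was chosen after its values were seen.

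Regions with shorter coverage at E14.5 were fewer and less certain. On chromosome X, the region from 121267284 to 121270265 was covered over 1988.5 bp ± 1405 at E12.5 and was called in neither E14.5 library (adjusted p = 0.013). The regions on chromosome 12 from 75904774 to 75905593 (781.5 bp ± 54.4 at E12.5, adjusted p = 0.02) and on chromosome 11 from 3097611 to 3099960 (737.5 bp ± 16.3, adjusted p = 0.021) were likewise called in neither E14.5 library. The chromosome 11 region was called again in all 4 adult libraries. None of these 3 passed without E14.5 replicate 1 (adjusted p = 0.121, 0.147 and 0.154 in the order named) or without E14.5 replicate 2 (0.126, 0.154 and 0.164). The chromosome 12 region also missed the threshold without E12.5 replicate 1 (0.0908), and the chromosome 11 region without E12.5 replicate 1 (0.0967) or replicate 2 (0.0563). Among the longer regions, the one on chromosome 7 missed it without E12.5 replicate 1 (0.0716), E14.5 replicate 1 (0.107) or E14.5 replicate 2 (0.13), and the one on chromosome 19 in lists of equal number (0.424). The regions on chromosomes 11 and 12 also missed it in lists of equal number (0.215 and 0.467), and the chromosome 11 region with a pseudocount of 1000 bp (0.0733).

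Over all regions, 3314 were called in both E14.5 libraries and neither E12.5 library (gained) and 28 the other way (lost). In the 2 other splits of these 4 libraries, at most 35 regions separated the sides. Of the 3314 gained regions, 1047 were called in both ISC libraries and 785 in both enterocyte libraries. This asymmetry was smaller in lists of equal number. With each list held to its 11111 strongest peaks, 394 regions were gained and 212 lost. Equal length pushes the 2 counts towards balance whatever the cause, so this setting cannot tell a true gain from a longer list. It kept every peak of E12.5 replicate 1, while E14.5 replicate 1 lost peaks although 11982 of its peaks had a −log10 q of at least 10. By covered bp, limma called 2689 regions longer and 329 shorter of 17679 tested, so that 89.1% of the changed regions were longer. The share was 99.8% without scaling, where the median log2 change of all regions was 0.735 against 0.191 with scaling, and 68.2% in lists of equal number (539 longer, 251 shorter). Quantile normalization gave 618 longer and 55 shorter, and a median log2 change of all regions of -0.083, opposite in sign. Among the 8903 regions called in all 8 libraries, 337 were longer and 307 shorter, but the scaling equalizes the medians over these same regions, so this near-even balance is no separate finding. The 329 shorter regions became 69 without E14.5 replicate 1, 60 without E14.5 replicate 2, 203 without E12.5 replicate 1 and 621 without E12.5 replicate 2. The 3314 gained regions became 5140 without E12.5 replicate 2. The 28 lost regions became 1027 without E12.5 replicate 1, 262 without E12.5 replicate 2 and 52 without E14.5 replicate 2.

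**Figure D2:**
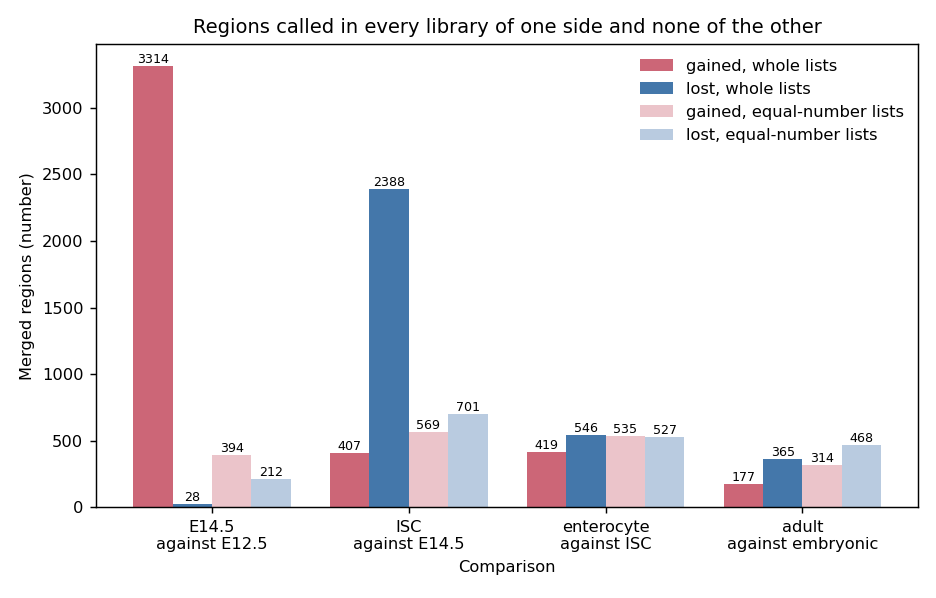
Number of merged regions called in every library of the first-named group and no library of the second (gained), or the reverse (lost), for the 4 comparisons, from the whole peak lists and from lists of equal number. From E12.5 to E14.5 the whole lists give 3314 gained and 28 lost regions, and lists of equal number give 394 and 212.

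Between E14.5 epithelium and adult stem cells, long regions were called on 1 side and not, or over little length, on the other, in both directions. The region on chromosome 14 from 80399966 to 80407772 was covered over 6941 bp ± 1225 (SD, n = 2) in ISC and was called in no library of the other 3 groups (limma, adjusted p = 2e-04). The regions on chromosome 1 from 132722753 to 132728336 (5324 bp ± 368 in ISC) and on chromosome 7 from 26259149 to 26262711 (3205 bp ± 358) were called in no embryonic library and in both enterocyte libraries (adjusted p = 2e-04 for both). Conversely, the region on chromosome 11 from 95862240 to 95869647 was covered over 7040.5 bp ± 520 at E14.5 and was called in neither ISC library (adjusted p = 0.00074). A further region of chromosome 11, from 18914382 to 18921110, was covered over 6550 bp ± 41 at E14.5 and 178.5 bp ± 252 in ISC, a log2 change of -4.06 ± 0.49 (SE, adjusted p = 0.0029). With 1 ISC library at 0 bp, the size of this change was uncertain: it was -3.37 without ISC replicate 1, -4.73 without ISC replicate 2, -2.43 with a pseudocount of 1000 bp and -5.26 with 50 bp.

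Another region, on chromosome 7 from 149840171 to 149851336, fell from 10957 bp ± 209 at E14.5 to 293 bp ± 414 in ISC (log2 change -4.54 ± 1.08, adjusted p = 0.047). This call was at the edge of the threshold. The change was -3.61 without ISC replicate 1, -5.45 without ISC replicate 2, -2.97 with a pseudocount of 1000 bp and -5.68 with 50 bp. The call was lost without E12.5 replicate 1 (adjusted p = 0.0933), E12.5 replicate 2 (0.0917), E14.5 replicate 1 (0.278), E14.5 replicate 2 (0.278), ISC replicate 1 (0.221) or ISC replicate 2 (0.0707). It was also lost with a pseudocount of 50 bp (0.137) and with regions called in at least 1 (0.0586) or at least 4 (0.0709) libraries tested. Regions called in all 8 libraries changed in length as well, in examples chosen after their values were seen. On chromosome 5, from 28784448 to 28795085, coverage fell from 10141 bp ± 89.1 at E14.5 to 1589.5 bp ± 607 in ISC, a log2 change of -2.27 ± 0.19 (adjusted p = 0.00068). On chromosome 17, from 15956582 to 15968581, coverage rose from 4585.5 bp ± 367 to 10538.5 bp ± 2067 (log2 change 1.44 ± 0.10, adjusted p = 0.00033), with 4697 bp ± 583 in enterocytes. On chromosome 11, from 98209414 to 98212520, coverage rose from 977.5 bp ± 16.3 to 3036 bp ± 100.4 (log2 change 1.70 ± 0.11, adjusted p = 0.00026), a call lost in lists of equal number (0.23) at the same change of 1.70. On chromosome 7, from 146097920 to 146102052, coverage fell from 3802.5 bp ± 261 to 859.5 bp ± 99.7 (log2 change -1.63 ± 0.11, adjusted p = 0.00033).

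Over all regions, 407 were called in both ISC libraries and neither E14.5 library and 2388 the other way. The 2 other splits of these 4 libraries separated at most 240 regions. Of the 407 gained regions, 179 were called in both enterocyte libraries and 17 in both E12.5 libraries. Of the 2388 lost regions, 386 were called in both E12.5 libraries and 39 in both enterocyte libraries. Lists of equal number gave 569 gained and 701 lost, a balance that equal length favours by construction. By covered bp, limma called 507 regions longer and 2099 shorter, 19.5% longer of those changed. That share was 42.2% with quantile normalization (604 longer, 828 shorter) and 43.2% in lists of equal number (546 longer, 719 shorter). The median log2 change of all regions was -0.33 without scaling, -0.07 with it and 0.026, opposite in sign, with quantile normalization. Among the 8903 regions called in all 8 libraries, 106 were longer and 96 shorter, a balance that the scaling over these regions favours. The 507 longer regions became 301 without E14.5 replicate 1. The 407 gained regions became 1652 without ISC replicate 1 and 814 without ISC replicate 2, and the 2388 lost became 3668 without E14.5 replicate 1 and 3761 without ISC replicate 2.

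**Figure D3:**
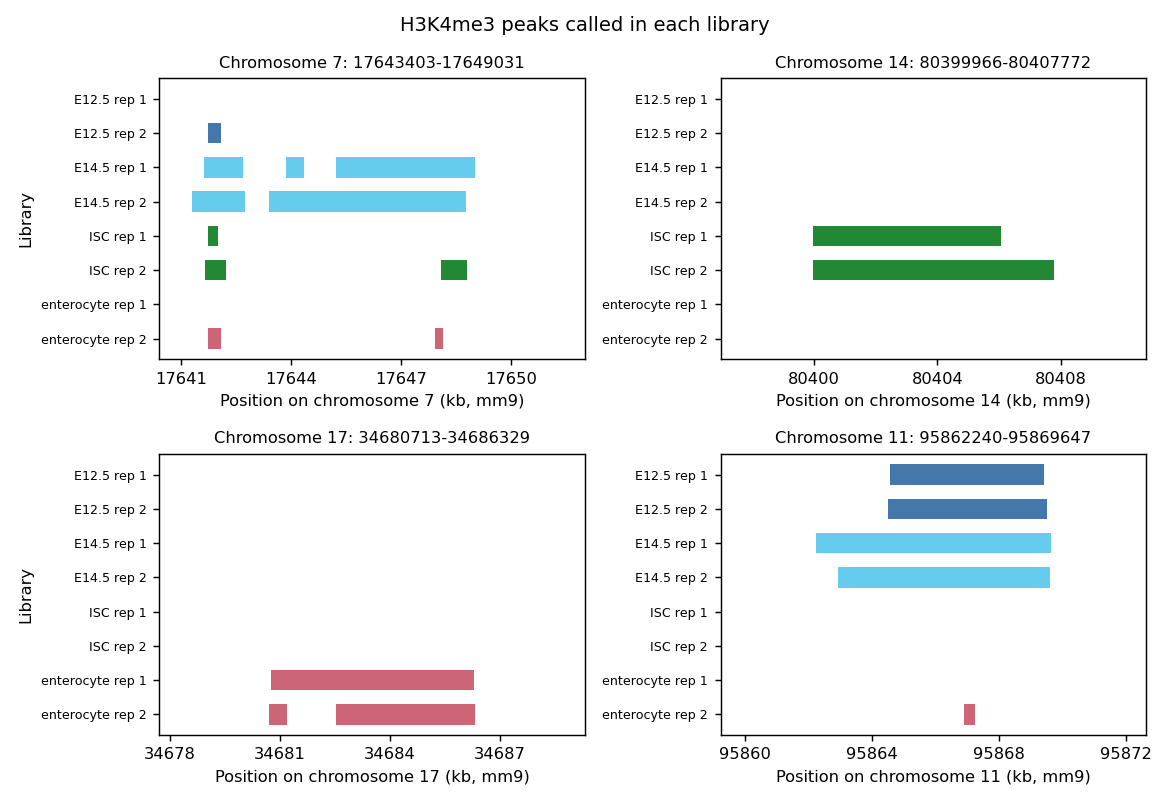
Peaks called in each of the 8 libraries (rows) around 4 regions, by mm9 position in kb: the regions with the largest fitted log2 increase, at a pseudocount of 200 bp, from E12.5 to E14.5 (chromosome 7), from E14.5 to ISC (chromosome 14) and from ISC to enterocytes (chromosome 17), and with the largest decrease in adult against embryonic libraries (chromosome 11). Bars are peaks, and an empty row has no peak there. The peaks at the left of the chromosome 7 panel belong to a separate merged region.

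From adult stem cells to enterocytes, long regions were called in enterocytes that were called in no embryonic library. The region on chromosome 17 from 34680713 to 34686329 was covered over 4909.5 bp ± 893 (SD, n = 2) in enterocytes and called in no other library (limma, adjusted p = 0.00044). The same held for the region on chromosome X from 160578567 to 160583345 (4364.5 bp ± 573.5, adjusted p = 4e-04). On chromosome 12, the region from 112654550 to 112664518 rose from 312.5 bp ± 442 in ISC to 9483.5 bp ± 155 in enterocytes, a log2 change of 4.64 ± 0.61 (SE, adjusted p = 0.011). The stem-cell region on chromosome 14 from 80399966 to 80407772 was called in neither enterocyte library (adjusted p = 0.00039). Also absent from both enterocyte lists were the regions on chromosome 2 from 103138900 to 103144514 (4906.5 bp ± 715 in ISC and 742 bp ± 102 at E14.5, adjusted p = 0.00045) and on chromosome 1 from 67158286 to 67163209 (4403 bp ± 495 in ISC, adjusted p = 0.00039).

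Among regions called in all 8 libraries, one on chromosome 7 from 148618895 to 148623773, chosen after its values were seen, rose from 649 bp ± 255 in ISC to 4075.5 bp ± 1136 in enterocytes (log2 change 2.38 ± 0.24, adjusted p = 0.0041). It was covered over 396.5 bp ± 146 at E12.5 and 1489 bp ± 271 at E14.5. With 1 ISC library at 0 bp, the change of the chromosome 12 region was 3.68 without ISC replicate 1, 5.59 without ISC replicate 2, 3.08 with a pseudocount of 1000 bp and 5.78 with 50 bp. With a pseudocount of 1000 bp, with quantile normalization, in lists of equal number, without ISC replicate 2 and without enterocyte replicate 1, it had a larger fitted change than the chromosome 17 region named first. The chromosome 12 call was lost without E14.5 replicate 1 (adjusted p = 0.0674), E14.5 replicate 2 (0.0671) or enterocyte replicate 1 (0.0685).

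Over all regions, 419 were called in both enterocyte libraries and neither ISC library and 546 the other way, 965 in all. A split of the same 4 libraries by replicate number separated 933 regions, so the total was close to that between replicates. Of the 419 gained regions, 39 were called in both E14.5 libraries and 0 in both E12.5 libraries. Of the 546 lost, 385 (70.5%) were called in both E14.5 libraries and 177 in both E12.5 libraries. Lists of equal number gave 535 gained and 527 lost, and peaks with a −log10 q of at least 10 gave 156 and 42. By covered bp, limma called 769 regions longer and 561 shorter. Among the regions called in all 8 libraries, 252 were longer and 140 shorter. Over all tested regions, the balance turned to 821 longer and 1727 shorter without enterocyte replicate 2, to 583 and 805 without ISC replicate 1, and to 307 and 348 among regions called in at least 4 libraries. Without E14.5 replicate 1 there were 451 longer and 331 shorter, and without E14.5 replicate 2 there were 454 and 336. The 419 gained regions became 3508 without enterocyte replicate 1 and 823 without ISC replicate 2. The 546 lost regions became 2107 without ISC replicate 1, 956 without ISC replicate 2 and 2101 without enterocyte replicate 2.

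Adult and embryonic epithelium differed at regions that were called on one side in every library. The region on chromosome 1 from 132722753 to 132728336 was covered over 5324 bp ± 368 in ISC and 4257.5 bp ± 497 in enterocytes (SD, n = 2 each) and called in no embryonic library (limma, adjusted p = 0.00018). The regions on chromosome 17 from 85077991 to 85085096 (2703 bp ± 243 in ISC and 6833 bp ± 304 in enterocytes, adjusted p = 6.8e-05) and on chromosome 7 from 26259149 to 26262711 (3205 bp ± 358 and 3418.5 bp ± 91.2, adjusted p = 0.00018) were likewise called in no embryonic library. In the other direction, the region on chromosome 11 from 95862240 to 95869647 was covered over 4934.5 bp ± 88.4 at E12.5, 7040.5 bp ± 520 at E14.5 and 164 bp ± 232 in enterocytes (adjusted p = 0.00036). The regions on chromosome 12 from 28022837 to 28028886 (5673 bp ± 62.2 at E12.5 and 5946 bp ± 147 at E14.5, adjusted p = 0.0014) and on chromosome 5 from 58105386 to 58111683 (4870.5 bp ± 223 and 6237 bp ± 86.3, adjusted p = 8.8e-05) were covered over 406.5 bp ± 575 and 276.5 bp ± 6.4 in ISC and called in neither enterocyte library. The chromosome 5 region missed the threshold in lists of equal number (adjusted p = 0.0607).

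Among regions called in all 8 libraries, 878 were longer and 705 shorter in adult epithelium. In examples chosen after their values were seen, coverage on chromosome 9 from 108755102 to 108763575 was 509 bp ± 99 at E12.5, 936 bp ± 67.9 at E14.5, 1768 bp ± 191 in ISC and 6898 bp ± 2229 in enterocytes (log2 change 2.03 ± 0.11 SE, adjusted p = 0.00036). On chromosome 9 from 121550271 to 121554721 it was 435.5 bp ± 347, 1339.5 bp ± 271, 2913.5 bp ± 602 and 3907 bp ± 769 in the same order (1.93 ± 0.26, adjusted p = 0.0032). The chromosome 5 region from 28784448 to 28795085, covered over 7911.5 bp ± 1232.5 at E12.5, was shorter in adult libraries by this comparison too (log2 change -2.60 ± 0.14, adjusted p = 0.00035).

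Over all regions, 177 were called in all 4 adult and no embryonic library and 365 in all 4 embryonic and no adult library. Lists of equal number gave 314 and 468. By covered bp, limma called 2423 regions longer and 3148 shorter in adult epithelium. Of these 5571 regions, 2142 had covered bp that did not overlap between the 4 adult and 4 embryonic libraries. A fit with these 2 groups alone, where differences within a side count as spread, called 404 longer and 619 shorter. The balance between longer and shorter depended on the setting: it was 2545 longer and 2375 shorter with quantile normalization, 2218 and 1980 in lists of equal number, and 1647 and 1376 among regions called in at least 4 libraries. The 2423 longer regions became 1474 without E14.5 replicate 1 and 1559 without E14.5 replicate 2. The 177 adult regions became 355 without ISC replicate 1, and the 365 embryonic regions became 845 without E12.5 replicate 1.

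In lists held to peaks with a −log10 q of at least 10, which left 1441 peaks for E12.5 replicate 1 and 11982 for E14.5 replicate 1, several of the named calls were lost. From E12.5 to E14.5 these were the regions starting at 67158286 on chromosome 1 (adjusted p = 0.141) and at 5841400 on chromosome 19 (0.441). From E14.5 to ISC they were those starting at 26259149 (0.889) and 146097920 (0.398) on chromosome 7, at 95862240 (0.208) and 98209414 (0.903) on chromosome 11, at 15956582 on chromosome 17 (0.883) and at 28784448 on chromosome 5 (0.794). From ISC to enterocytes they were those starting at 67158286 on chromosome 1 (0.998) and at 148618895 on chromosome 7 (1.0). For adult against embryonic epithelium they were those starting at 26259149 on chromosome 7 (0.112), 95862240 on chromosome 11 (0.117), 28022837 on chromosome 12 (0.137), 108755102 on chromosome 9 (0.153) and 28784448 on chromosome 5 (0.601). Of these 15 lost calls, 9 had a smaller fitted change than with the whole lists and 6 a larger one. A further 8 named calls were not tested there, since their regions were called in fewer than 2 of these lists: the 3 shorter regions from E12.5 to E14.5, the chromosome 14 region in both of its comparisons, and the regions starting at 112654550 on chromosome 12, 160578567 on chromosome X and 103138900 on chromosome 2.

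Across the 4 groups, 12189 regions were called in both or neither library of every group. Of these, 8903 were called in all 4 groups, 1289 at E14.5 alone, 624 in all groups but E12.5 and 369 in enterocytes alone. A further 365 were called in both embryonic groups alone, 177 in both adult groups alone, 174 in all groups but enterocytes, 128 at E14.5 and in ISC alone, 115 in ISC alone and 6 at E12.5 alone. In lists of equal number, the E14.5 regions numbered 80 and the E12.5 regions 139, while the enterocyte regions numbered 479 and the embryonic regions 468. A fixed list length limits the regions of a group with long lists by construction. The median covered length was 1417.5 bp for regions in all groups, 430.5 bp for E14.5 regions, 786.5 bp for enterocyte regions and 404 bp for ISC regions.

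**Figure D4:**
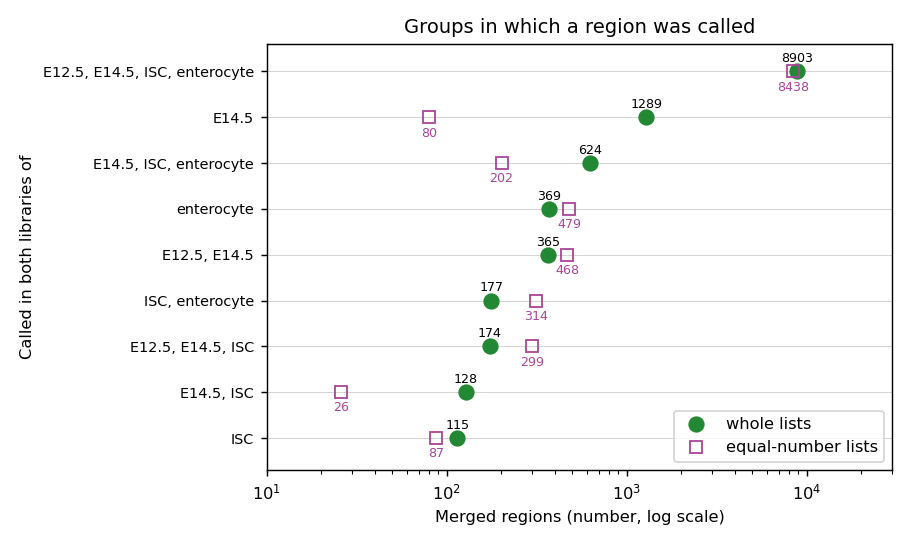
Number of merged regions (log axis) called in both libraries of the groups named on the vertical axis and in no other library, for patterns with at least 100 regions, from the whole peak lists (filled circles) and lists of equal number (open squares). Regions of E14.5 alone number 1289 in the whole lists and 80 in lists of equal number.

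The widest H3K4me3 domains were largely shared by replicates. Merged regions holding 1 of the 500 widest peaks of both libraries numbered 422 at E14.5, 373 in ISC, 344 in enterocytes and 341 at E12.5. Divided by 500, these were 84.4% (95% Wilson interval 81 to 87.3), 74.6% (70.6 to 78.2), 68.8% (64.6 to 72.7) and 68.2% (64 to 72.1). A region can hold several of these peaks, so the values are not shares of peaks and the intervals are approximate. In both libraries of every group, 84 regions ranked among the 500 widest. In both libraries of 1 group and no other library, 115 did so in enterocytes, 62 at E12.5, 40 at E14.5 and 37 in ISC. Ranks were taken within each list and do not measure a change between groups.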

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

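The named regions kept their direction in all 546 alternatives run for them, and the adjusted p rose above 0.05 in 45, of which 21 left out a library and 24 were other settings. Both results were favoured by the choice of regions, which were named for large changes without overlap between the groups' libraries. Those called in all 8 libraries were kept only if they passed with each library left out, so these runs could not fail. The difference in Jaccard index passed its test under every alternative, at 0.117 for shared regions and 0.181 in lists of equal number. Counts were less stable, and the causes of the following changes were not tested beyond what the construction of a setting shows. For peaks with a −log10 q of at least 10, E12.5 replicate 1 retained 1441 peaks and E14.5 replicate 1 retained 11982, so this setting compares lists of very different length. It gave 0 shorter regions for E14.5 against E12.5 by limma (14 at an unadjusted p under 0.05), 14 longer and 1390 shorter for ISC against E14.5, 146 and 23 for enterocytes against ISC, and 705 and 1367 for adult against embryonic. Gained and lost regions were 5129 and 0 for E14.5 against E12.5 and 156 and 42 for enterocytes against ISC, with 11 gained for ISC against E14.5, and 6 adult and 12 embryonic. Both libraries shared 1424 regions at E12.5, 6193 in ISC and 5309 in enterocytes. It also ended 15 of the 33 calls of named regions and left 8 untested; 5 were untested among regions in at least 4 libraries and 2 in lists of equal number.

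Lists of equal number gave 539 longer (E14.5 against E12.5), 719 shorter (ISC against E14.5) and 1980 shorter (adult against embryonic) regions, 394 gained and 212 lost for E14.5 against E12.5, 701 lost for ISC against E14.5, and 314 adult regions. Requiring 500 covered bp left 14 lost for E14.5 against E12.5 and 232 gained for ISC against E14.5. For E14.5 against E12.5, no scaling gave 8098 longer and 20 shorter, quantile normalization 618 and 55, regions in at least 1 library 171 shorter, and regions in at least 4 libraries 939 longer and 101 shorter. Quantile normalization gave 828 shorter for ISC against E14.5. Testing regions in at least 4 libraries, which leaves fewer regions to test, gave 264 and 484 for ISC against E14.5, 307 and 348 for enterocytes against ISC, and 1376 shorter for adult against embryonic. Regions holding 1 of the 1000 widest peaks of both libraries numbered 727 at E12.5, 72.7% when divided by 1000.

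Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave ranges of 1870 to 3761 longer and 60 to 621 shorter regions for E14.5 against E12.5, 301 to 615 and 1706 to 2398 for ISC against E14.5, 451 to 827 and 331 to 1727 for enterocytes against ISC, and 1474 to 2795 and 2188 to 3655 for adult against embryonic. Gained and lost regions ranged from 3398 to 5140 and 30 to 1027, from 430 to 1652 and 2434 to 3761, from 448 to 3508 and 607 to 2107, and from 177 to 355 and 365 to 845, in the same order; a rule with fewer libraries lets at least as many regions through by construction. The replicate numbers were not taken to pair the libraries: correlations of replicate differences across regions were 0.021 to 0.311 over the 6 pairs of groups, all positive and highest for ISC and enterocytes. With replicate number as a block, limma gave 2684 longer and 368 shorter, 485 and 2056, 701 and 494, and 2415 and 3175 regions in the same order, and the Jaccard difference of 0.176 was the largest of 24 pairings (exact permutation p = 0.0417). Promoter windows of other sizes and the gene list tests were not run, since no annotation of the build was used. A total of 6673 regions were called in 1 library only, and the lists give no signal for the other libraries there.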

Other observations

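Some tests in this part were chosen only after the results were seen: the exact tests of the X chromosome, the X difference over regions of the embryonic libraries, the comparisons of single E14.5 and E12.5 lists, the splits of gained and lost regions, and the test of neighbouring regions. Regions called in enterocytes alone lay near each other more often than random sets of regions did. The random sets were drawn from regions called in at least 2 but not all 8 libraries. They were not matched for length or strength, and they also served for the distances to constant regions below. Of these 369 regions, 22.0% had another one within 100 kb, against 7.0% (95% range 3.8 to 10.8) in 1000 random sets drawn from the same chromosomes (two-sided permutation p = 0.001, the smallest they can give, adjusted 0.0033 over 10 tests). Whether neighbouring regions change together stays open, since this test restates the excess it was chosen from. For embryonic regions the share was 7.7% against 7.1% (permutation p = 0.83), and for ISC regions 3.5% against 3.5%. For E14.5 regions it was 23.0% against 20.0% (permutation p = 0.045, adjusted 0.075), and for regions of both adult groups alone 7.3% against 3.4% (permutation p = 0.032, adjusted 0.064). One run of enterocyte regions held 4 regions on chromosome 19 from 3929016 to 4048042. A run of 3 regions called in both adult groups alone lay on chromosome 17 from 34422807 to 34515881, and a run of 10 regions called at E14.5 alone lay within 73.4 kb on chromosome X from 47903178 to 47976579.

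Enterocyte regions also lay close to constant ones: 14.4% were within 5 kb of a region called in all 8 libraries, against 6.8% in random sets (4.3 to 9.2, permutation p = 0.001, adjusted 0.0033). Embryonic regions went the other way, with 1.6% against 6.3% (3.8 to 8.8, permutation p = 0.001, adjusted 0.0033), as did E14.5 regions, with 4.3% against 6.4% (adjusted permutation p = 0.005). For ISC regions the share was 9.6% against 6.1%, and for regions of both adult groups alone 9.0% against 6.2% (adjusted permutation p = 0.2 for both). Part of the enterocyte regions may thus be edges of longer domains; the 14.4% sets no bound on that part, since domains called in fewer libraries were not counted.

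The asymmetry from E12.5 to E14.5, with 3314 regions gained and 28 lost, was followed up first. Lower depth at E12.5 is argued against as the whole cause for 1 pair of libraries only. Replicates 2 had 22696869 tags at E12.5 and 22718162 at E14.5. Of the regions called in only 1 of these 2 lists, 82.8% (5000 against 1039, 95% Wilson interval 81.8 to 83.7) were in the E14.5 list. The 2 E14.5 replicates were skewed as well, with 1657 regions in replicate 2 only and 329 in replicate 1 only, although replicate 1 had more tags. Such a skew thus arises within a stage too, and the skew of this pair does not show a difference between stages. More regions differed between the stages (5000 and 1039) than between the E14.5 replicates (1657 and 329). That larger number rests on 1 pair of libraries and does not tell stage from enrichment. The gained regions were weak in the E14.5 lists, with a median percentile by −log10 q of 19.8 in the list of replicate 2. For regions called at both stages it was 69.7, and 17 of the 3314 gained regions lay above percentile 50. Weak regions missed in the E12.5 lists would give this. However, regions gained from E14.5 to ISC (20.0) and lost from ISC to enterocytes (19.9) were as weak in the list of ISC replicate 2. Not every changed set was: regions gained from ISC to enterocytes had 29.9 in the list of enterocyte replicate 2. Under the stricter rule of 4 libraries a side, embryonic regions had 37.5 (E14.5 replicate 2) and adult regions 38.5 (enterocyte replicate 2). Since other sets were as weak, the percentile does not single out E12.5. Lower enrichment at E12.5 stays a candidate that it cannot decide. Strong regions decide nothing: of those above percentile 50 in both E14.5 lists 0.101% (8 of 7957) were missing from both E12.5 lists, a rule stricter than the one behind the highest share of 0.237% between replicates, and for single lists the shares were 0.942% and 1.523% missing from E12.5 replicate 1 but 0.211% and 0.206% missing from replicate 2. A gain of weak marks between the stages stays open, because the lists hold no signal for regions that were not called.

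Regions called in both embryonic groups and no adult library held more X regions, 26 of 365 (7.12%), than regions called in all 8 libraries did (251 on X and 8651 on autosomes, 2.82%; two-sided Fisher's exact p = 4.6e-05, adjusted 0.00056 over 12 patterns). The excess was not particular to them: the X share was 7.47% (13 of 174, adjusted exact p = 0.0067) in all groups but enterocytes, 6.25% (8 of 128, 0.092) at E14.5 and in ISC alone, and 2 of 2 (0.0048) at E12.5 and in ISC alone. Regions near each other are not independent, and with those within 100 kb counted once the embryonic numbers were 23 and 327 against 161 and 3736 (Fisher's exact p = 0.039, adjusted 0.11; 0.021 for the 2 of 2), so an uneven draw by chance stays open. A lower X signal in all adult libraries stays open too. The measure was X minus autosomes in median adult minus embryonic log2 covered bp. Over regions called in all 4 embryonic libraries it was -0.085 (95% bootstrap interval -0.14 to -0.05), on both sides of the -0.1 set for it. These regions include the embryonic X regions whose excess is in question, so this value partly restates that excess. The test set beforehand, over regions called in all 8, gave -0.043 (-0.083 to -0.008) and met the bound set against this explanation. That bound was wrong, since such regions leave out those lost in adults, and the interval lies below 0 as this explanation predicts. Both intervals draw regions as if independent and hold no spread between libraries, so neither decides the question. The adult mice were males and the sex of the embryos is not given in the sources used here; Y regions numbered 24 and 18 at E12.5, 6 and 9 at E14.5, 33 and 30 in ISC and 27 and 8 in enterocytes, and sex and stage stay open as untested explanations.

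In ISC and enterocytes, 922 regions were called in both replicates 2 and neither replicate 1, and 11 the other way. These regions were weak, with a median percentile of 21.8 in the list of enterocyte replicate 2, as the lower depth of the replicate 1 libraries would give; lower enrichment would give the same. A batch shared by libraries of the same number cannot be told apart from this: the median E14.5 difference (replicate 2 minus replicate 1) over these regions was 0.0. That value had been set beforehand as evidence against a batch, but the regions went both ways (429 longer in replicate 2, 243 in replicate 1 and 250 in neither E14.5 list, mean 0.144), and without the 250 the median was 0.087, between the bounds set, so it decides nothing. Of the regions in 1 E14.5 list, 84 were in replicate 2 and 19 in replicate 1, against 1657 and 329 over all regions. No biological explanation was tested.

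For adult against embryonic epithelium, chance was examined over the 35 splits of the 8 libraries into 4 and 4. In a fit with 2 groups, the real split gave 1023 changed regions and the highest other split 6, and 1 of 35 splits, the real one, reached that number. For gained and lost regions the real split gave 542 and the highest other 328, again with 1 of 35 splits as large. This argues against a random grouping of single libraries only. Splits that keep replicates together number 3, too few for a test; the other 2 gave 1 and 6 changed regions, and 37 and 128 gained and lost regions.

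Most regions lost from E14.5 to ISC were weak as well. The median percentile of the 2388 regions in the list of E14.5 replicate 2 was 21.2, and 64 lay above percentile 50. Of the 7957 regions above percentile 50 in both E14.5 lists, 41 (0.515%, 95% Wilson interval 0.38 to 0.698) were missing from both ISC lists. The highest share between replicates was 0.237%, under a less strict rule of 1 list each, and lies below this interval. The interval holds counting error only, and no bound was set for this comparison beforehand. Replicate pairs do not span the difference between E14.5 and ISC libraries, such as 43259380 tags in E14.5 replicate 1 and 13355462 in ISC replicate 1. Shares for single E14.5 and ISC lists were not computed. Whether missed regions are the source of these 41 is therefore not decided.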
